A study of Mus musculus with 24 samples.

How the data were processed

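Hippocampal RNA of 24 mice was measured on 24 Agilent 1-colour microarrays in 6 groups of 4: controls and fear-conditioned mice aged 3 and 16 months, and context and shock-context mice aged 3 months. Per the labels, 600 ng of total RNA from each mouse was labelled with Cy3. Per the file headers, the authors' scanner files come from Agilent Feature Extraction 9.5.3.1 and hold signal intensity for each spot: the processed signal (background subtracted and corrected for spatial trends, with no scaling between arrays), the mean and background signals, and marks for outlier spots and for spots well above background. The deposited table holds values of the authors that were taken to be log2, from the values themselves and not from a label: each of its columns follows the rank order of that array's median spot signal (Spearman 1) and all columns share a median of 8.57, as after quantile normalization over all arrays. It was used as an alternative.

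For the main analysis the processed signal was taken to log2 and each array's 75th percentile was subtracted. Control spots were left out, outlier spots were set to missing, spots of the same probe were averaged, and probes well above background on at least 4 of 24 arrays were kept. The probe with the highest mean stood for each gene, which left 26580 genes, 18637 of them with a symbol. Probe positions are those of the mm9 build in the file headers. Group means of all 24 arrays were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 18 residual degrees of freedom, and 10 comparisons were tested by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The SE beside a log2 change is that of the fit. Genes tied to the association are those past the threshold, in the same direction, in young fear against control, context and shock-context.

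The comparisons, settings and 27 gene lists were fixed before the data were examined. The lists were immediate early genes, later activity-regulated genes, glucocorticoid-induced genes, histone acetyltransferases, histone deacetylases, formins and actin regulators, glutamate receptors and postsynaptic density, presynaptic vesicle release, voltage-gated ion channels, microglia and complement, antigen presentation and interferon response, oxidative phosphorylation, cytosolic ribosomal proteins, heat shock and unfolded protein response, cholesterol synthesis, neurogenesis and cell division, sex-linked genes, and markers of astrocytes, oligodendrocytes and myelin, interneurons, hippocampal excitatory neurons, choroid plexus, blood cells, endothelial and mural cells, thalamus, striatum and neocortex. Some genes stand in more than 1 list, such as Calb2, Slc17a6 and Inf2 among the thalamus markers and Enpp2 among the choroid plexus markers. Each list was tested against all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation, under which 2 of 87 calls held: thalamus markers in old fear against old control, and microglia and complement in old against young control. Limma's fry, which asks whether members move one way on balance, served as a second test. Genes named in the text are part of a set fixed by rule: the 8 largest rises and 8 largest falls past the threshold among genes with a symbol and well above background on every array of at least 1 group, up to 4 members of smallest adjusted p from each list, and a fixed panel of Fos, Arc, Egr1, Npas4, Nr4a1, Dusp1, Sgk1, Fmn2, Prkca, Gfap and C4b. Where fewer than 5 genes passed, the rule allowed those of smallest p, which are not named here.

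Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, no filter and a stricter filter, outlier spots kept, every probe tested, the deposited values, the slide as random or fixed block, eBayes with trend and robust, only the compared arrays, and each array left out in turn. The control and fear arrays lie on 4 slides with 1 array of each group per slide, and the slide served as replicate block there. Replicate numbers were checked for pairing: 15 of 24 same-numbered pairs in the control and fear groups had a correlation over 0.1, with a range of -0.41 to 0.65, so the numbers were not taken to pair mice across groups, and the fit with the replicate number as block is an alternative. After the data were seen, arrays 1 and 2 and arrays 3 and 4 of each control and fear group were also averaged, or used as a random block with a consensus correlation of 0.37.

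The fit was tested on simulated data with changes added to 50 genes at each size: 40 of 50 were recovered at a log2 change of 1 and 40 at -1, 13 at 0.5 and 12 at -0.5, 4 of 26351 unchanged genes were called, and 0 were called where no gene was changed. A choroid plexus shift of -0.5 was recovered by camera and 0 other lists were called. The simulated noise was independent between genes and between arrays. The false calls counted here therefore do not cover correlated genes or the array pairs. No gene-level counts of molecules exist for these arrays, so their number sets the precision. One gene that passed between the control groups is not reported here by name.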

Results

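Gene expression was measured in the hippocampus of 24 mice, each on its own Agilent 1-colour microarray, in 6 groups of 4. Mice aged 3 or 16 months were either handled controls or were taken 1 h after contextual fear conditioning, in which 3 min in a new chamber ended with a foot shock of 0.7 mA for 2 s. A further pair of groups, aged 3 months, had the same chamber without any shock (context) or a shock immediately on entry, before they could explore it (shock-context). The 16 control and fear arrays were scanned in a first run, with a 75th percentile of signal of 757 to 2137 and 86.6 to 94.0% of probes well above background. The 8 context and shock-context arrays were scanned in a second run, at 3101 to 8369 and 75.5 to 81.7%. The number of arrays limits the precision throughout. In each control and fear group, arrays 1 and 2 lay close together, as did arrays 3 and 4, so p-values that treat the 4 arrays as independent may be too small. Counts with these array pairs as a random block are given beside the others.

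Fear conditioning at 3 months was compared with handling alone, to find the genes that respond to training in young mice. Fos, an immediate early transcription factor gene switched on by neuronal activity, was 5.32-fold higher after training (log2 change 2.41 ± 0.29 SE, n = 4 arrays per group, adjusted p = 1.52e-06; probe on chromosome 12, 86817900 to 86817959 in build mm9). All 4 trained arrays lay above all 4 control arrays for Fos. Of the 32 immediate early genes measured, 8 rose and 5 fell, and 13 passed adjusted over the list alone. Over all genes 11487 of 26580 passed, a similar share, so the number of calls does not set this list apart. Fosl2 rose by 0.72 ± 0.15 and Dusp1, which encodes a phosphatase of MAP kinases, by 0.47 ± 0.14 (adjusted p = 0.0105, and 0.117 with the array pairs averaged). Klf6 fell by 1.08 ± 0.10 and Arl4d fell by 1.86 ± 0.30. Better known members did not pass: Egr1 at 0.47 ± 0.19 (adjusted p = 0.0547), Arc at 0.41 ± 0.26 (0.196), Nr4a1 at 0.24 ± 0.24 (0.418) and Npas4 at -0.08 ± 0.24 (0.803), the last with its sign turned under median scaling. Egr1 passed under median scaling (adjusted p = 0.0414). The list lay 0.49 above the median of all genes (camera adjusted p = 0.0129, but adjusted p = 0.572 with an estimated correlation).

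Single genes of synapses, chromatin and the actin skeleton passed in the same comparison, as did 11487 of all 26580 genes. The member counts below are to be read beside that share. With an estimated correlation camera called 0 lists in this comparison. Fmn2, which encodes an actin-nucleating formin, was 1.75-fold higher (0.81 ± 0.12, adjusted p = 2.52e-05; chromosome 1, 176751781 to 176751840), and Prkca, the gene of protein kinase C alpha, was 2.50-fold higher (1.32 ± 0.15, adjusted p = 5.23e-07). Of 41 formins and actin regulators, 11 rose and 6 fell, Cttn rising by 1.21 ± 0.13 and Fmnl1 by 1.25 ± 0.18 while Cdc42 fell by 1.10 ± 0.13 (17 passed adjusted over the list alone; list camera adjusted p = 0.00616, but adjusted p = 0.0991 with an estimated correlation). Of 27 histone deacetylases and their partners, 10 rose, among them Hdac4 by 1.13 ± 0.10 and Sirt2 by 0.76 ± 0.07, and 5 fell, among them Sin3b at -1.45 ± 0.14 and Sirt3 at -1.03 ± 0.10. In this list 15 passed adjusted over the list alone, with a camera adjusted p = 0.0129, but adjusted p = 0.0991 with an estimated correlation. Of 22 histone acetyltransferases 7 rose, with Kat6b at 0.78 ± 0.09 and Kat7 at 0.58 ± 0.09, and 6 fell (13 adjusted over the list alone; camera adjusted p = 0.27). Of 46 genes of presynaptic vesicle release 18 rose and 8 fell (28 adjusted over the list alone; camera adjusted p = 0.000805, but adjusted p = 0.0991 with an estimated correlation). Among them the vesicular glutamate transporter gene Slc17a7 rose by 1.93 ± 0.23 and the dynamin gene Dnm1 by 1.28 ± 0.13. Of 45 voltage-gated ion channel genes 14 rose, Kcnh7 by 1.19 ± 0.16 and Cacna1e by 1.22 ± 0.18, and 3 fell. In this list 16 passed adjusted over the list alone, with a camera adjusted p = 0.000805, but adjusted p = 0.281 with an estimated correlation. Of 49 genes of glutamate receptors and the postsynaptic density 14 rose and 15 fell (31 adjusted over the list alone; camera adjusted p = 0.109). Dlg4, the gene of PSD-95, rose by 2.29 ± 0.23, while Grm5 fell by 1.71 ± 0.17 and Camk4 fell by 1.64 ± 0.16. Ddn, which encodes dendrin, rose by 2.12 ± 0.15.

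Markers of tissue that borders the hippocampus and housekeeping genes changed as well. Of 29 markers of the choroid plexus, the epithelium that makes cerebrospinal fluid, 28 fell and 0 rose. Adjusted over the list alone 28 passed, and their median was 2.51 below that of all genes (camera adjusted p = 2.08e-15, but adjusted p = 0.113 with an estimated correlation). Ttr, the transthyretin gene, was 28.4-fold lower (-4.83 ± 0.46; chromosome 18, 20832612 to 20832672), and Kcne2 at -4.89 ± 0.40, Steap1 at -4.82 ± 0.33, Aqp1 at -4.54 ± 0.37 and Clic6 at -4.13 ± 0.32 moved alike. Of 26 thalamus markers 15 rose and 1 fell, and 16 passed adjusted over the list alone. Prkcd rose by 2.09 ± 0.14, Rab37 by 1.67 ± 0.15 and Rora by 1.07 ± 0.18, and Ntng1 stood at -0.80 ± 0.14. For this list camera adjusted p = 3.49e-07, but adjusted p = 0.0991 with an estimated correlation. Of 77 genes of oxidative phosphorylation 65 fell and 1 rose, and the complex subunits Ndufa1 and Cox7a2 lay at -1.78 ± 0.12 and -1.79 ± 0.12. Of 80 cytosolic ribosomal protein genes 70 fell and 2 rose, with Rps13 at -1.56 ± 0.09 (67 and 72 adjusted over the list alone). These lists lay 0.52 and 0.51 below all genes (camera adjusted p = 1.92e-16 and 1.80e-16, but adjusted p = 0.0991 with an estimated correlation for both). With quantile normalization 52 members of each still fell. Gfap, the astrocyte filament gene, rose by 1.33 ± 0.15 and Glul fell by 1.67 ± 0.11.

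**Figure D1:**
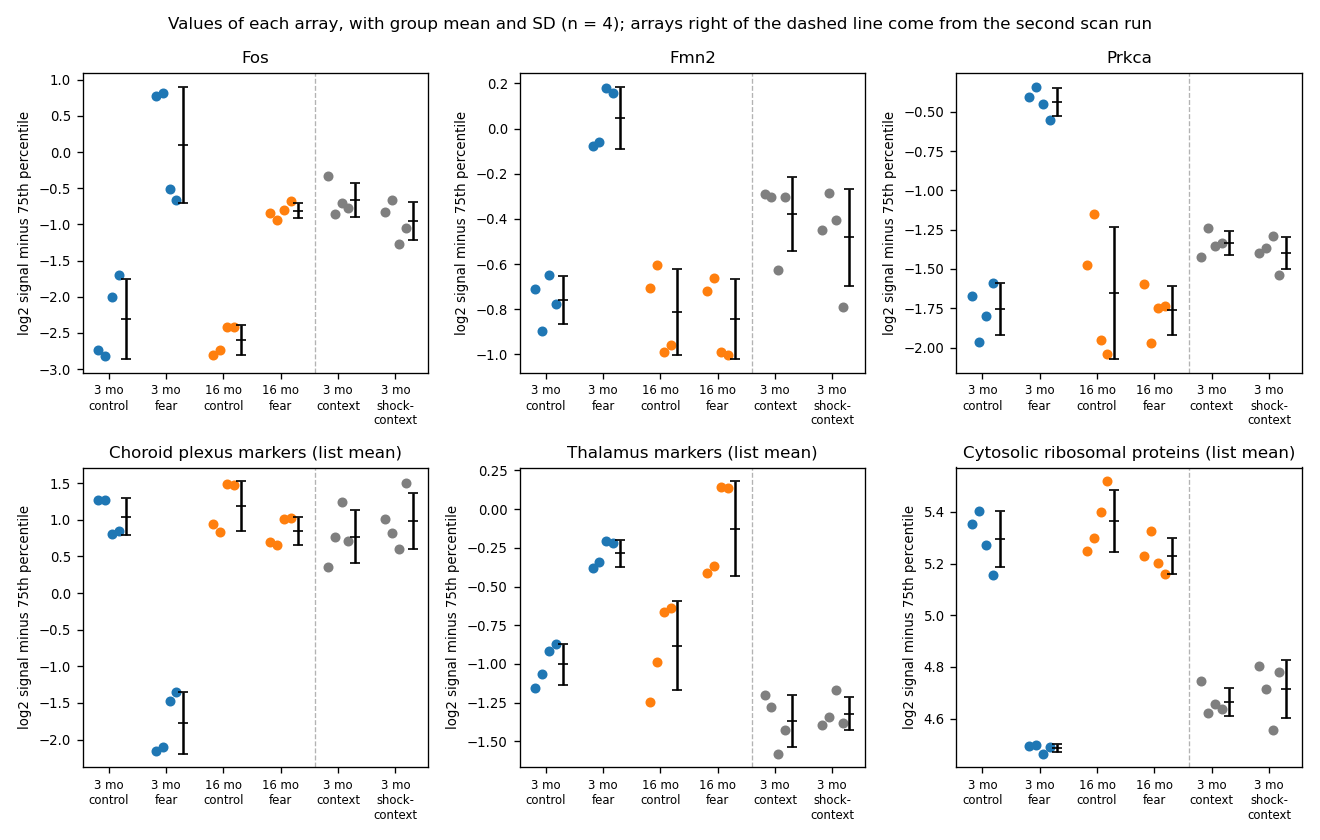
Values of each array (points, log2 signal minus the array's 75th percentile) for Fos, Fmn2 and Prkca and for the means of the choroid plexus, thalamus and ribosomal protein lists in the 6 groups, with the group mean and SD (n = 4). In the choroid plexus panel the 4 young fear arrays lie between -2.16 and -1.36, below the arrays of the other groups, the lowest of which is at 0.36.

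Among the other lists in this comparison, antigen presentation and interferon genes fell relative to all genes, with 19 of 37 lower and 1 higher. In this list 20 passed adjusted over the list alone, with a camera adjusted p = 0.0425, but adjusted p = 0.649 with an estimated correlation. Bst2 fell by 1.67 ± 0.16 and Psmb9 fell by 1.06 ± 0.13. Interneuron markers lay above all genes, with 8 of 24 higher and 7 lower. In this list 17 passed adjusted over the list alone, with a camera adjusted p = 0.0425, but adjusted p = 0.0991 with an estimated correlation. The other lists had camera adjusted p of 0.109 or more. Fry, which does not compare a list with other genes, called 20 lists, 10 of them not called by camera, and did not call the immediate early list (adjusted p = 0.285). Of 28 later activity-regulated genes 5 rose and 9 fell, with Homer1 at 0.95 ± 0.14 and Crem at -0.65 ± 0.10. Nrgn in that list, at -0.84 ± 0.13, did not pass under quantile normalization (adjusted p = 0.0728). Of 22 glucocorticoid-induced genes 4 rose and 7 fell, with Per1 at 0.81 ± 0.11, Mt2 at -1.73 ± 0.13 and Pdk4 at -0.94 ± 0.15. Sgk1 was uncalled at 0.20 ± 0.12 (adjusted p = 0.17). Of 31 microglia and complement genes 3 rose and 14 fell, with C4b uncalled at 0.06 ± 0.12 (adjusted p = 0.713). Of 24 astrocyte markers 4 rose and 9 fell, of 28 oligodendrocyte and myelin markers 7 rose and 9 fell. Of 33 genes of neurogenesis and cell division 4 rose and 12 fell. Of 30 hippocampal excitatory neuron markers 6 rose and 9 fell, of 18 blood cell markers 1 rose and 9 fell. Of 35 endothelial and mural markers 7 rose and 11 fell. Of 22 striatum markers 3 rose and 7 fell, of 30 neocortex markers 4 rose and 10 fell. Of 30 heat shock and unfolded protein response genes 4 rose and 13 fell. Of 25 cholesterol synthesis genes 2 rose and 11 fell, and of 5 sex-linked genes 1 rose and 1 fell.

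Across the array, 11487 of 26580 genes passed after fear conditioning at 3 months, 3501 higher and 7986 lower. The count was 8714 with the array pairs as a random block and 14490 with the slide as replicate block. Each named gene is read from 1 probe. Of 1330 genes with 2 called probes in this comparison, 28.1% had probes of opposite sign. Larger rises among genes with a symbol included Adamts19 (2.55 ± 0.27) and Ntn1 (2.34 ± 0.18). Cdkl4 rose as well (2.83 ± 0.35), but was well above background on 1 of 4 control arrays, so the size of this rise rests on values near background. The median of all genes lay at -0.34, and relative to it Fos changed by 2.76. Among the genes named above, this moved the following changes by over 1.5 times or turned their sign. Falls became smaller for Crem (-0.31), Nrgn (-0.49), Pdk4 (-0.60) and Ntng1 (-0.46). Rises became larger for Dusp1 (0.82), Kat7 (0.93), Egr1 (0.81), Arc (0.76), Nr4a1 (0.58), Sgk1 (0.55) and C4b (0.40), and Npas4 turned to 0.27. The share of higher genes was 30.5% with the 75th percentile, 44.8% with median scaling and 44.2% with quantile normalization, under which the median of all genes lay at -0.20 and -0.14. The count was 5352 with another background correction, under which the calls of Ntn1, Adamts19, Cdkl4, Kcnh7, Cacna1e and Dusp1 were lost.

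At 16 months, fear conditioning was compared with handling at that age. Fos was 3.44-fold higher (1.78 ± 0.29, n = 4 arrays per group, adjusted p = 0.0107), and Egr2 was 3.30-fold higher (1.72 ± 0.31, adjusted p = 0.0214). Sgk1, a kinase gene induced by glucocorticoids, was 1.70-fold higher (0.76 ± 0.12, adjusted p = 0.00872). The calls of Egr2 and Sgk1 were lost with the array pairs as a random block (adjusted p = 0.0636 and 0.0597) and with the slide as replicate block (0.113 and 0.082), and that of Fos with the slide (0.131). Of 32 immediate early genes 2 rose and 0 fell, and 5 passed adjusted over the list alone, 4 higher and 1 lower. For this list camera adjusted p = 0.000354, but adjusted p = 0.611 with an estimated correlation. Uncalled members were Egr1 at 0.74 ± 0.19 (adjusted p = 0.12), Arc at 0.51 ± 0.26 (0.382), Nr4a1 at 0.54 ± 0.24 (0.318), Dusp1 at 0.32 ± 0.14 (0.317) and Npas4 at -0.10 ± 0.24 (0.882). Fmn2 at -0.03 ± 0.12 (0.935) and Prkca at -0.11 ± 0.15 (0.778) did not pass either.

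Thalamus markers, which mark tissue bordering the hippocampus, were the clearest group after conditioning at 16 months. Whether their rise at either age reflects training or the amount of thalamus in the dissected tissue was not tested. Of 26, 6 rose and 0 fell, and 17 passed adjusted over the list alone, with a median change of 0.64 (camera adjusted p = 1.49e-21, and adjusted p = 0.00389 with an estimated correlation). Rab37 rose by 1.57 ± 0.15 (adjusted p = 1.14e-05; chromosome 11, 115023290 to 115023349), Synpo2 by 1.85 ± 0.29, Tnnt1 by 2.20 ± 0.41, Prkcd by 0.86 ± 0.14 and Adarb1 by 0.52 ± 0.08. Outside that list Adamts19 rose by 2.31 ± 0.27 (adjusted p = 0.00023) and Tafa4 by 2.12 ± 0.36, both well above background on 3 of 4 old control arrays, and Patj by 1.35 ± 0.13 (adjusted p = 1.88e-05). Ccdc153 fell by 0.84 ± 0.17 and Rarres2 fell by 0.64 ± 0.12. The microglial gene Tmem119 fell by 0.44 ± 0.08 and Rab5c fell by 0.42 ± 0.08. These 4 had adjusted p of 0.0256 to 0.0476, and none was past the threshold under median scaling. Choroid plexus markers lay lower by camera, with 0 members past the threshold over all genes and 2 adjusted over the list alone (median -0.44, camera adjusted p = 0.00047, but adjusted p = 0.611 with an estimated correlation). The same p of 0.611 with an estimated correlation held for lower ribosomal (camera adjusted p = 6.90e-06), oxidative phosphorylation (0.00487), myelin (0.00487), antigen presentation (0.0074) and microglia (0.0152) lists and for a higher neocortex list (0.0287). With quantile normalization the ribosomal and oxidative phosphorylation shifts were lost (adjusted p = 0.381 and 0.751). Of the 9 lists called by camera, fry called 1, the thalamus markers (adjusted p = 4.53e-05).

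In all, 38 genes passed at 16 months, 33 higher and 5 lower, while 3664 had an unadjusted p under 0.05. The count was 11 with the array pairs as a random block, 18 with the slide as replicate block, 0 with another background correction and 137 with quantile normalization. The share of higher genes was 86.8%, against 97.3% with median scaling and 80.3% with quantile normalization. The count fell to 7 without old fear array 4, which ended the call of Fos (adjusted p = 0.0588). It was 17, 21 and 19 without old fear arrays 2 and 3 and old control array 4, and 116 without old control array 1. Rab37, Adamts19 and Patj passed in each of these leave-outs and in both blocked fits, but missed with the array pairs averaged (adjusted p = 0.0737, 0.295 and 0.0585), under which 1 gene passed in all. With the array pairs as a random block Tnnt1, Tafa4 and Adarb1 missed (adjusted p = 0.069, 0.101 and 0.0923), as did the 4 lower genes named above (0.219 to 0.348). With the slide as replicate block Prkcd and Adarb1 missed (0.0715 and 0.141), as did those 4 (0.106 to 0.145).

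The response to training was then compared between the ages, as the difference between the old and the young change. The change at 16 months lay below that at 3 months for Fmn2, by -0.84 ± 0.18 (n = 4 arrays per group, adjusted p = 0.00152, and 0.0729 with the array pairs averaged). The same held for Prkca (-1.43 ± 0.21, adjusted p = 5.63e-05), Hdac4 (-1.18 ± 0.14), Sirt2 (-0.74 ± 0.10), Kat6b (-0.74 ± 0.13), Kat7 (-0.67 ± 0.13) and Gfap (-1.42 ± 0.21, adjusted p = 5.41e-05). The synaptic genes Dlg4 (-2.76 ± 0.32), Ddn (-2.39 ± 0.21) and Slc17a7 (-2.07 ± 0.32) differed in the same direction. So did Fkbp5 (-1.12 ± 0.26, adjusted p = 0.0549 with the array pairs averaged). Klf6 (1.10 ± 0.14), Mt2 (1.60 ± 0.18) and Sin3b (1.21 ± 0.20), which fell at 3 months, differed in the other direction. No difference between the ages passed for Fos (-0.63 ± 0.41, adjusted p = 0.311) or Arc (0.10 ± 0.36, adjusted p = 0.882). That of Sgk1 (0.56 ± 0.17, adjusted p = 0.0187) was lost with median scaling (adjusted p = 0.0961) and with the array pairs as a random block (0.0623).

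Gene lists were also tested for the difference between the ages, which contains the young change with its sign turned. Of 29 choroid plexus markers 26 differed upward. Likewise 53 of 77 oxidative phosphorylation genes and 55 of 80 ribosomal protein genes differed upward, with 0 and 2 downward (26, 59 and 65 adjusted over the list alone). The medians were 2.19, 0.55 and 0.52 above all genes (camera adjusted p = 9.18e-16, 9.18e-16 and 1.38e-14, but adjusted p = 0.175 with an estimated correlation for each). Histone deacetylases (4 up and 8 down of 27), formins and actin regulators (4 and 8 of 41) and presynaptic genes (3 and 12 of 46) differed downward relative to all genes. Adjusted over the list alone 13, 12 and 20 passed (camera adjusted p = 0.0235, 0.0251 and 0.00719, but adjusted p = 0.175 with an estimated correlation for each). Voltage-gated channels (4 and 7 of 45) and myelin markers (6 and 9 of 28) did so too (16 and 15 adjusted over the list alone; camera adjusted p = 0.0164 and 0.0235, but adjusted p = 0.602 and 0.603 with an estimated correlation). The presynaptic median itself was 0.05 with a mean of -0.09, so its sign depends on the summary. In all 6347 genes differed, 4205 upward and 2142 downward. The count was 4297 with the array pairs as a random block, 6721 with the slide as replicate block and 2367 with the pairs averaged. It was 0 with the pairs averaged and the slide pair as replicate block, so each interaction call named above was lost there. Fry called 12 lists, 5 of them called by camera too. The share upward was 66.3%, against 54.2% with median scaling and 54.1% with quantile normalization, and the median of all genes lay at 0.23. Relative to it Sgk1 lay at 0.33 and Arc at -0.14.

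Compared directly after training, the hippocampus of 16-month-old mice had higher levels of microglial and immune transcripts than that of 3-month-old mice. Of 31 microglia and complement genes 21 were higher and 1 lower, with Cd52 higher by 2.03 ± 0.13 (n = 4 arrays per group), C4b by 1.55 ± 0.12 and Ctss by 1.41 ± 0.13. In this list 22 passed adjusted over the list alone, with a camera adjusted p = 0.000121, but adjusted p = 0.282 with an estimated correlation. Antigen presentation genes were higher in 20 of 37 and lower in 0. In this list 21 passed adjusted over the list alone, with a camera adjusted p = 0.000378, but adjusted p = 0.417 with an estimated correlation. Fos was lower by a log2 change of -0.92 ± 0.29 (adjusted p = 0.0171), a call lost with the slide as block (0.058) and without young fear array 1 (0.078) or 2 (0.0796). Fmn2 (-0.89 ± 0.12), Prkca (-1.33 ± 0.15), Dlg4 (-2.27 ± 0.23), Ddn (-2.25 ± 0.15), Hdac4 (-1.22 ± 0.10), Sirt2 (-0.81 ± 0.07), the acetyltransferase gene Ep300 (-0.77 ± 0.12) and Gfap (-0.75 ± 0.15) were lower. Ttr (4.63 ± 0.46) and Kcne2 (4.55 ± 0.40) were higher with 26 of 29 choroid plexus markers (0 lower), as were 63 of 77 oxidative phosphorylation and 68 of 80 ribosomal genes (1 lower in each). Formins (14 lower and 5 higher of 41), presynaptic genes (16 and 8 of 46), voltage-gated channels (16 and 2 of 45), deacetylases (11 and 5 of 27) and endothelial markers (8 and 6 of 35) lay lower relative to all genes. Adjusted over the list alone, 27, 65 and 72 members of the first 3 of these lists passed, and 19, 24, 18, 16 and 14 of the others. These 8 shifts passed by camera (adjusted p of 0.0252 or less), and with an estimated correlation adjusted p = 0.131 or more for each. Fry called 17 lists, 10 of them called by camera too. In all 10058 genes differed, 6582 higher and 3476 lower, and the count was 7975 with the array pairs as a random block and 11508 with the slide as replicate block. The median of all genes lay at 0.26. The share higher was 65.4%, against 56.1% with median scaling and 53.9% with quantile normalization.

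Age alone was compared between the handled controls, as the background to the training effects. C4b, the gene of complement component 4, was 3.31-fold higher at 16 months (1.73 ± 0.12, n = 4 arrays per group, adjusted p = 3.27e-08; chromosome 17, 34866361 to 34866420). C3 was 3.11-fold higher (1.64 ± 0.18, adjusted p = 5.06e-05) and the leukocyte gene Cd52 was 2.31-fold higher (1.21 ± 0.13, adjusted p = 3.81e-05). Of 31 microglia and complement genes 7 rose with age and 0 fell, and 23 passed adjusted over the list alone, C1qa among them at 0.64 ± 0.09. The list's median was 0.41 (camera adjusted p = 9.52e-31, and adjusted p = 0.0024 with an estimated correlation). Antigen presentation genes shifted upward, with 2 of 37 past the threshold, Psmb8 at 0.56 ± 0.10 and Ifit3 at 0.64 ± 0.12, and 12 adjusted over the list alone. Their camera adjusted p = 4.34e-12, but adjusted p = 0.117 with an estimated correlation. Myelin markers did so with Trf at 0.69 ± 0.15 as the 1 member past the threshold and 8 adjusted over the list alone (camera adjusted p = 2.74e-11, but adjusted p = 0.0959 with an estimated correlation). Among astrocyte markers Gfap rose by 0.67 ± 0.15 (adjusted p = 0.0308; 2 members adjusted over the list alone, list camera adjusted p = 0.0256, but adjusted p = 0.2 with an estimated correlation).

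Of 33 genes of neurogenesis and cell division 3 were lower past the threshold at 16 months. Dcx, the doublecortin gene of immature neurons, fell by 0.64 ± 0.11 (adjusted p = 0.00502), the proliferation gene Mki67 fell by 0.54 ± 0.10 and the nucleotide reductase gene Rrm2 fell by 0.65 ± 0.12. These 3 calls were lost with the array pairs as a random block (adjusted p = 0.0593, 0.0865 and 0.0808), and those of Dcx and Rrm2 also with the slide as replicate block (0.054 and 0.0801). Adjusted over the list alone 6 members passed, 1 of these higher, and the list lay lower by camera (adjusted p = 0.00377, but adjusted p = 0.117 with an estimated correlation). Rrm2 was uncalled under median scaling (adjusted p = 0.0809) and turned its sign with another background correction. Slco1a4 in the endothelial list (-0.39 ± 0.09; 4 members adjusted over the list alone, list camera adjusted p = 0.00631, but adjusted p = 0.117 with an estimated correlation) was lower. The neocortex list lay lower too (4 members adjusted over the list alone, camera adjusted p = 0.0229, but adjusted p = 0.171 with an estimated correlation). Choroid plexus and ribosomal lists lay higher with 0 members past the threshold, also adjusted over the list alone (camera adjusted p = 0.03 and 0.000271, but adjusted p = 0.748 and 0.708 with an estimated correlation). Larger rises, beside those of C4b and C3, included Sult1c2 (2.14 ± 0.25), Erdr1 (1.72 ± 0.23), Cox8b (1.54 ± 0.30), Prom2 (1.47 ± 0.17) and Dlk1 (1.44 ± 0.24). Larger falls included Wdfy1 (-1.69 ± 0.10, adjusted p = 1.32e-09), Creb3l3 (-1.49 ± 0.33), Cyp2f2 (-1.46 ± 0.32), Trim68 (-1.34 ± 0.24), Nfya (-1.30 ± 0.23), Gabra2 (-1.26 ± 0.27) and Pbk (-1.25 ± 0.19). However, the mean of Wdfy1 was -0.38 in the context and shock-context mice, also young, near the -0.40 of the old control and fear arrays. Those young arrays come from the second scan run, so for Wdfy1 this comparison does not settle an effect of age. With the array pairs as a random block Psmb8, Ifit3, Trf and Gfap missed (adjusted p = 0.0682, 0.0644, 0.178 and 0.109), as did Slco1a4 (0.254), Cox8b (0.0731), Creb3l3 (0.0936), Cyp2f2 (0.0887), Trim68 (0.0731) and Gabra2 (0.0865). With the slide as replicate block Ifit3 (0.0528), Slco1a4 (0.143), Creb3l3 (0.19), Trim68 (0.0776) and Nfya (0.0905) missed. In all 184 genes passed, 118 higher and 66 lower, and 2560 had an unadjusted p under 0.05. The count was 41 with the array pairs as a random block, 100 with the slide as replicate block and 4 with the pairs averaged, C4b and Wdfy1 among these, or 0 with the slide pair as replicate block as well. Fry called 8 lists, 7 of them called by camera too. The count ran from 81 without old control array 4 to 291 without old control array 2, with 96 without old control array 3 and 101 without young control array 2. The share of higher genes was 64.1%, or 74.0% with median scaling.

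**Figure D2:**
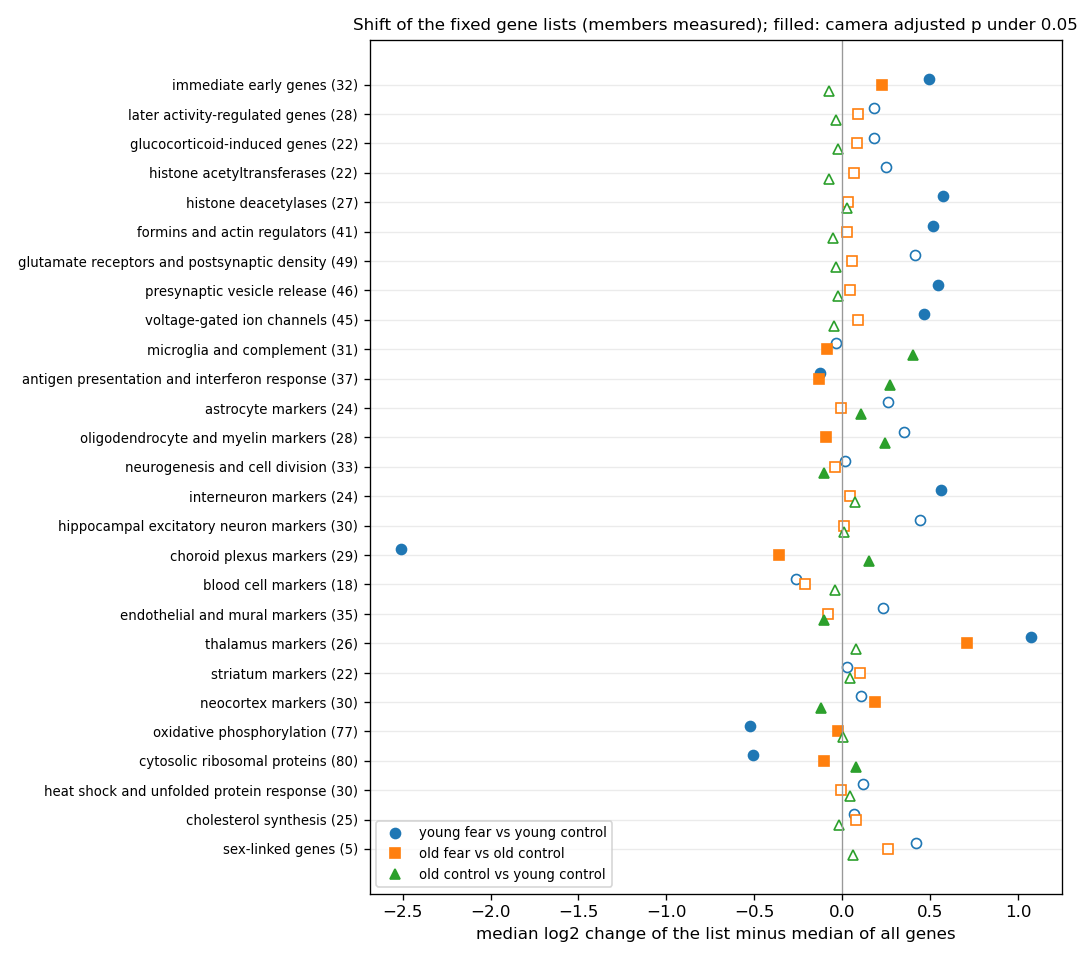
Median log2 change of each fixed gene list minus the median of all genes (horizontal axis) for young fear against young control (circles), old fear against old control (squares) and old against young control (triangles), with filled symbols where camera's adjusted p was under 0.05. Choroid plexus markers lie at -2.51 in the young fear comparison, and thalamus markers lie above all genes in both fear comparisons.

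Context and shock-context mice were compared with handled controls, for a chamber without shock and for a shock that could not be linked to the chamber. All arrays of these 2 groups come from the second scan run and all controls from the first, so none of the differences below can be told apart from the scan run. Fos was 3.13-fold higher in context mice (1.65 ± 0.29, n = 4 arrays per group, adjusted p = 4.49e-05) and 2.57-fold higher in shock-context mice (1.36 ± 0.29, adjusted p = 0.000373) than in controls. Genes induced by glucocorticoids rose in 9 and 11 of 22 and fell in 5 and 4. Sgk1 rose by 0.98 ± 0.12 and 1.01 ± 0.12, Per1 by 1.04 ± 0.11 and 1.09 ± 0.11, and Txnip by 0.78 ± 0.10 and 0.82 ± 0.10, while Mt2 was at -1.27 ± 0.13 and -1.16 ± 0.13. Adjusted over the list alone 14 and 15 members passed (camera adjusted p = 0.00121 and 0.000308, but adjusted p = 0.272 and 0.151 with an estimated correlation). Npas4 was lower at -0.97 ± 0.24 and -0.91 ± 0.24, and Klf6 at -0.87 ± 0.10 in context mice. The median of all genes lay at -0.48 in context and -0.42 in shock-context mice, so a large part of these falls is shared by all genes. Relative to that median Npas4 lay at -0.49 and -0.50, Klf6 at -0.39, Mt2 at -0.79 and -0.74, and Txnip at 1.26 and 1.24. Dusp1 rose by 0.35 ± 0.14 in context mice (adjusted p = 0.0358), a call that several leave-outs ended (adjusted p = 0.139 without young context array 1), and stood at 0.26 ± 0.14 in shock-context mice (0.12). Egr1 at 0.30 ± 0.19 and 0.31 ± 0.19 (adjusted p = 0.168 and 0.162) passed under median scaling (0.0167 and 0.0126). Arc at 0.22 ± 0.26 and -0.08 ± 0.26 (0.463 and 0.797) did not pass under that scaling in shock-context mice (0.31).

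Fmn2 was higher by 0.38 ± 0.12 in context mice (adjusted p = 0.0102) and stood at 0.28 ± 0.12 in shock-context mice (0.0558, and 0.00019 under median scaling). Prkca was higher by 0.42 ± 0.15 and 0.36 ± 0.15 (adjusted p = 0.0148 and 0.0361, 0.145 and 0.178 with another background correction, and 0.054 in shock-context mice with the array pairs as a random block). Endothelial and mural markers shifted upward, with 14 and 13 of 35 higher and 7 lower in each. Of these members 21 and 20 passed adjusted over the list alone (camera adjusted p = 0.00108 and 0.00181, but adjusted p = 0.125 and 0.122 with an estimated correlation). Of 77 oxidative phosphorylation genes 59 fell in each comparison, and of 80 ribosomal protein genes 63 and 65 fell, with Rps13 at -0.96 ± 0.09 and -0.90 ± 0.09. In the first list 62 and 61 members passed, and in the second 65 and 69, adjusted over the list alone (camera adjusted p of 0.0201 or less for the 4 shifts, but adjusted p = 0.559 or more with an estimated correlation). The immediate early list lay above all genes in both (camera adjusted p = 0.0155 and 0.0255, but adjusted p = 0.499 and 0.451 with an estimated correlation). However, 8 members fell in each against 6 and 4 that rose (12 and 10 adjusted over the list alone) and its means were -0.002 and -0.02. Camera called 8 lists in context and 14 in shock-context mice, 6 and 12 of them above all genes and 0 with an estimated correlation. Several of these had medians below 0, such as later activity-regulated genes at -0.11 and -0.04 (camera adjusted p = 0.0494 and 0.0447, but adjusted p = 0.499 and 0.41 with an estimated correlation). Among the larger rises Synpo, which encodes the actin-associated synaptopodin, was higher by 3.55 ± 0.41 and 3.42 ± 0.41, and Gnal, a G protein gene, by 3.17 ± 0.25 and 2.99 ± 0.25. Tmem52b was at least 17.3-fold lower in context mice. Of the 8 largest falls among genes with a symbol, 5 in context and 6 in shock-context mice were of olfactory or vomeronasal receptor genes. Of the same 8, 7 and 8 were well above background on 0 arrays of the context or shock-context group.

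In all 18699 genes passed between context and control, 3784 higher and 14915 lower, and 17748 between shock-context and control, 3293 higher and 14455 lower. Counts were 17760 and 16737 with the array pairs as a random block and 15263 and 15892 with the replicate number as block. Group and scan run cannot be told apart in these counts, and no value within a run can be had. Fry called 19 and 15 lists, 4 and 5 of them called by camera too. Relative to the median of all genes Rps13 lay at -0.48 in each, Fmn2 at 0.86 and 0.70, Prkca at 0.90 and 0.78, Egr1 at 0.78 and 0.73, Dusp1 at 0.83 and 0.67, and Arc at 0.70 and 0.34. The share of higher genes was 20.2 and 18.6%, against 39.3 and 42.1% with median scaling and 37.3 and 37.9% with quantile normalization.

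Young fear mice were compared with the context and shock-context mice to find genes tied to the association of chamber and shock. Fos was higher after fear conditioning by 0.77 ± 0.29 than in context mice (n = 4 arrays per group, adjusted p = 0.0263, and 0.103 under median scaling) and by 1.05 ± 0.29 than in shock-context mice (0.00377). The call of Fos against context was also lost with the array pairs averaged (adjusted p = 0.0717). Fosb was higher by 1.67 ± 0.25 and 1.35 ± 0.25, and Npas4 by 0.89 ± 0.24 and 0.84 ± 0.24. Npas4 did not pass in young fear against control (-0.08), so it is not among the genes tied to the association. Its differences here follow its lower values in context and shock-context mice (-0.97 and -0.91 against control), which come from the second scan run. Prkca was higher by 0.90 ± 0.15 and 0.96 ± 0.15, Gfap by 1.08 ± 0.15 and 1.01 ± 0.15, and Fmn2 by 0.43 ± 0.12 and 0.53 ± 0.12, the latter calls being lost under median scaling (adjusted p = 0.149 and 0.0557). Glucocorticoid-induced genes were lower in 9 and 10 of 22 and higher in 2 and 1, Sgk1 at -0.78 ± 0.12 and -0.81 ± 0.12 and Plin4 at -1.32 ± 0.14 and -1.30 ± 0.14. In each 11 passed adjusted over the list alone (camera adjusted p = 0.000285 and 6.93e-05, but adjusted p = 0.233 and 0.234 with an estimated correlation). Sgk1 did not pass in young fear against control either (0.20), while it was higher in context and shock-context mice (0.98 and 1.01 against control). It is thus not among the genes tied to the association. Scan run and group cannot be told apart in any of these differences.

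Choroid plexus markers were lower after fear conditioning in these comparisons as well, 27 of 29 in each with 1 higher, and Ttr lay at -4.89 ± 0.46 and -5.08 ± 0.46. In each 28 passed adjusted over the list alone (camera adjusted p = 3.15e-18 and 4.53e-20, but adjusted p = 0.233 and 0.234 with an estimated correlation). The thalamus marker Prkcd was higher by 2.27 ± 0.14 and 2.09 ± 0.14, with 17 of 26 list members higher and 2 lower in each (21 and 19 adjusted over the list alone; camera adjusted p = 0.0749 and 0.0908). Tnnt1 was higher by 3.33 ± 0.41 than in context mice. Of the 8 largest rises among genes with a symbol, 3 against context and 5 against shock-context were of olfactory or vomeronasal receptor genes. Of the same 8, 7 and 8 were well above background on 0 arrays of the second run. Fry called 17 and 15 lists, 6 of them in each called by camera too. The nuclear noncoding RNA gene Malat1 was lower at -4.86 ± 0.27 and -4.43 ± 0.27. In all 17529 genes passed against context, 12630 higher and 4899 lower, and 17253 against shock-context, 12363 higher and 4890 lower. Counts were 16359 and 15998 with the array pairs as a random block and 15451 and 16835 with the replicate number as block. Scan run and group cannot be told apart in either, and the median of all genes lay at 0.33 and 0.31. Relative to it Fos was higher by 0.44 than in context mice, Npas4 by 0.56 and 0.53, Fmn2 by 0.10 and 0.22, and Prkca by 0.57 than in context mice. The share higher was 72.1 and 71.7%, against 60.2 and 56.9% with median scaling and 60.2 and 58.2% with quantile normalization. A set of 4852 genes changed in young fear mice against controls and in the same direction against both other groups, 1990 higher and 2862 lower, or 4001 with the array pairs as a random block. The scan run enters this set through both comparisons.

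Context and shock-context mice, which share the second scan run, were compared with each other to show the effect of a shock on entry. Of 26580 genes 0 passed in limma, with 1351 at an unadjusted p under 0.05, and 0 passed with the slide or the replicate number as block. Fos stood at 0.28 ± 0.29 (n = 4 arrays per group, adjusted p = 0.999), Arc at 0.30 ± 0.26 (0.993), Fmn2 at 0.10 ± 0.12 (0.999), Npas4 at -0.06 ± 0.24 and Sgk1 at -0.03 ± 0.12. Egr1 stood at -0.01 ± 0.19. Camera placed the choroid plexus, oxidative phosphorylation and cholesterol synthesis lists lower and the endothelial list higher in context mice (adjusted p = 0.0157, 0.0157, 0.0295 and 0.0294, but adjusted p = 0.833, 0.832, 0.504 and 0.423 with an estimated correlation). Each had 0 members past the threshold, over all genes or adjusted over the list alone, and fry called 0 lists.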

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

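The tests of the 3 patterns weighed here were chosen only after the results were seen, and the splits of the arrays were planned. After fear conditioning in young mice the ribosomal and oxidative phosphorylation lists fell. Old arrays as bright did not show this level. Within the young fear range of the 75th percentile (1543 to 2137), 3 of 3 old arrays had ribosomal means of 5.16 or more. The highest young fear array stood at 4.50. These old arrays reached only 1732, however, and the young controls, at 892 to 1361, were all dimmer than the young fear arrays. Brightness and training therefore cannot be told apart among the young control and fear arrays. Probe-specific labelling or hybridisation effects stay possible. Of the 1330 genes with 2 called probes 28.1% (374) had probes of opposite sign, although transcript variants were not tested as a source of this. That share is over all genes and not these lists, and it was 21.7 to 26.8% in the other comparisons with large counts. It therefore does not decide whether such effects lie behind this fall. A response to training stays open: 0 of the control arrays had a ribosomal mean as low as the young fear arrays, but training cannot be told apart from anything else that sets these 4 arrays apart. A low level was not particular to them. The ribosomal mean was 4.665 in context and 4.713 in shock-context mice, against 5.296 in young controls. The oxidative phosphorylation mean was 4.143 and 4.224, against 4.801. Those arrays come from the brighter second scan run, which cannot be told apart from group.

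Choroid plexus markers also fell in young fear mice, by -2.51 relative to all genes, so the shift shared by all genes does not account for it. A different amount of choroid plexus in the dissected tissue may be the source: over the 20 arrays of the other groups the 29 markers varied together from array to array, with a median pairwise correlation of 0.677, against 0.033 for the median of 10000 random lists and 0.234 for the highest of them, with 0 as high. Genes of this list are correlated in any tissue that holds it in varying amounts, and Ttr lay at -4.83. The random lists were matched to the markers by signal level only and not by cell type. The correlation therefore does not tell a varying amount of tissue from markers that change together within it. A loss of expression within the choroid plexus after training was not tested.

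In the control and fear groups arrays 1 and 2, and arrays 3 and 4, lay closest of the 3 possible pairings in 4 of 4 groups over 227 genes of 9 lists (chance 0.037 for any of the 3 pairings, since this one was picked after the values were seen). That chance treats the 4 groups as independent, though they share their slides. Slide shifts common to the groups do not account for the pairing, since it stayed closest in 4 of 4 groups with slide means removed. Slide effects that differ between groups were not tested. Labelling of 2 arrays from the same RNA or pool, or joint handling of 2 mice, may be behind the pairing, and the labels name 1 mouse per array. With the pairs as a random block 8714 genes passed in young fear, 11 in old fear and 41 for age.

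Values in 12 of 246 combinations of measure and group stood far from the other 3 arrays of their group, where chance gives 12.3. Egr1 stood at 2.68 on young control array 3 (nearest 3.16) and at 3.04 on young context array 2 (nearest 3.48). Fmn2 stood at -0.63 on young context array 3 (nearest -0.30). The mean of histone deacetylases was 1.20 on young context array 4 (nearest 1.23), and that of formins and actin regulators was 1.29 on old control array 2 (nearest 1.57) and 1.63 on young fear array 1 (nearest 1.68). Voltage-gated ion channels stood at -0.064 on shock-context array 3 (nearest -0.21), microglia and complement at -0.74 on shock-context array 4 (nearest -0.95), antigen presentation at -1.08 on young context array 2 (nearest -1.23), striatum markers at -1.16 on shock-context array 1 (nearest -0.97) and ribosomal proteins at 4.46 on young fear array 3 (nearest 4.49). Young context array 3 had 350 outlier spots (nearest 120).

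The response to training differed between the ages by the interaction in 6347 genes, and in the fixed panel for Sgk1 (0.56, adjusted p = 0.0187), Fmn2 (-0.84, adjusted p = 0.00152), Prkca (-1.43, adjusted p = 5.63e-05) and Gfap (-1.42, adjusted p = 5.41e-05). The call of Sgk1 was lost with the array pairs as a random block and that of Fmn2 with the pairs averaged. With the pairs averaged and the slide pair as replicate block, every interaction call was lost. In 100 random regroupings within each age, the real one included, 4 gave as many genes, the highest other 7901. The 3 others as large kept the real young grouping, and the highest without it gave 101. The count thus follows the young response, and these regroupings do not decide whether chance explains a difference between the ages.

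Other splits of the 8 arrays of a comparison, 35 in each, were counted. For young fear against control 1 split, the real one, gave as many genes (11487, highest other 54), and the same holds for old against young fear (10058, highest other 6). Chance is an unlikely source of both counts if the 8 arrays are independent, though 1 of 35 is the smallest share these splits can give. If the array pairs are the units, each comparison has 3 splits, too few for a share under 0.05 (real 11487 and 10058, highest other 54 and 6), and with the pairs averaged 7391 and 6541 genes passed. Only the real split gave as many genes for context against control (1 of 35, 18699, highest other 6850) and shock-context against control (1 of 35, 17748, highest other 3701). The same held for fear against context (1 of 35, 17529, highest other 6617) and fear against shock-context (1 of 35, 17253, highest other 5). In these comparisons the other splits mix both scan runs within groups, so the splits do not decide whether chance or the scan run explains the counts. For the 4852 association genes 1 of 100 regroupings of the 16 young arrays, the real one, gave as many (highest other 0). The other regroupings mix both scan runs within groups, while the real one keeps the runs apart. They therefore do not decide whether chance explains this set. For old fear against control 2 of 35 splits gave 38 genes or more, so chance cannot be excluded: arrays 1 and 2 of both groups against arrays 3 and 4 gave 184, which follows the array pairs. For old against young control 3 of 35 did (184 genes), the highest being 1063 for old arrays 1 and 2 with young arrays 3 and 4, several times the real count, which points to a structure of the arrays by pairs. For context against shock-context the real count was 0, so all 35 splits are as large whatever the data, which says nothing about chance. There the split of slide 5 against slide 6 gave 2707, and the real comparison with the slide as block gave 0.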

How the results depend on the processing

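Alternatives by the array pairs, chosen after seeing the data, are named as such below; the others were planned, and the cause of a change was not tested except where fewer arrays enter. Of 293 counts of genes or lists under alternatives 249 stayed within 1.5 times the reported count, of 235 list results 176 kept their call and direction and 59 lost the call, 45 of them with an estimated correlation, and of 4425 values for named genes 4007 kept direction and call, 357 lost the call, 23 gained it and 38 turned their sign, all 38 for genes that did not pass or, for Rrm2, that lost the call. No filter, outlier spots kept and eBayes with trend and robust moved no count beyond 1.5 times. With quantile normalization old fear against control gave 137 genes and context against shock-context 1. With normexp background young fear against control gave 5352, old fear 0, age 16, old against young fear 5503, the interaction 2009, fear against context 9858, fear against shock-context 8012 and the association genes 2287. With the stricter filter, which tests fewer genes, old fear gave 61 and shock-context against control 11793. With every probe tested, which counts probes, young fear gave 17307, old against young fear 15455, the interaction 10032 and the association genes 7794. With the slide as random block old fear gave 145 and age 361. With only the compared arrays, which leaves fewer arrays for the spread, old fear gave 3 and age 14. With the slide as replicate block old fear gave 18 and age 100. With an estimated correlation 2 of 87 list shifts were called. With the array pairs averaged, which leaves fewer replicates, young fear gave 7391, old fear 1, age 4, old against young fear 6541 and the interaction 2367. With the array pairs as a random block old fear gave 11 and age 41. With the pairs averaged and the slide pair as replicate block, old fear, age and the interaction gave 0 each and old against young fear 5894. Leaving out each array gave 7 (without old fear array 4) to 116 (without old control array 1) genes for old fear, 81 (without old control array 4) to 291 (without old control array 2) for age, and 0 to 1 for context against shock-context. Signs that turned under quantile normalization were those of Arc in shock-context against control (0.089) and in the interaction (-0.194) and of Egr1 (0.049) and Sgk1 (0.019) in context against shock-context. Under median scaling they were those of Npas4 in young fear (0.066), Fmn2 in old fear (0.034) and Arc in shock-context (0.298), and with normexp background those of Rrm2 with age (0.109), Egr1 (0.031) and Sgk1 (0.016) in context against shock-context and Arc in the interaction (-0.056). With the deposited values they were those of Npas4 in young fear (0.037) and old fear (0.079), Prkca in old fear (0.085), Arc in shock-context (0.048) and the interaction (-0.29), and Egr1 (0.105) and Sgk1 (0.089) in context against shock-context. Leaving out each array, signs turned within these ranges: in young fear Npas4 -0.226 to 0.12 and C4b -0.001 to 0.111, in old fear Npas4 -0.318 to 0.154, Prkca -0.237 to 0.061 and Fmn2 -0.09 to 0.041, Arc -0.286 to 0.126 in shock-context and -0.11 to 0.302 in the interaction, and in context against shock-context Egr1 -0.062 to 0.107, Npas4 -0.09 to 0.009 and Sgk1 -0.116 to 0.044. Signal over background limits the second scan run most, where 75.5 to 81.7% of probes were well above background.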

Other observations

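Genes that changed after fear conditioning and after context or shock exposure overlapped, in comparisons that share the young controls. Among higher genes 1575 were shared with context, where independent lists of these sizes would share 498, and 1443 with shock-context, against 434. Among lower genes 5432 were shared with context, against 4481, and 5135 with shock-context, against 4343. With the controls divided so that no array served both comparisons, the median shared counts were 1136.5 and 1025 higher genes, where independent lists of those sizes would share 354 and 298, and 3673 and 3344.5 lower genes, against 3201 and 3077. The shared count lay above that of independent lists in 6 of 6 divisions of the controls, except for lower genes with shock-context, where it did in 5. In most of these divisions both parts held an array of each array pair. If such pairs share RNA, the comparisons were not fully separate there. The scan run differs between the groups in both overlaps.

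The mean of thalamus markers was -1.0 ± 0.13 (SD, n = 4) in young controls and -0.88 ± 0.29 in old controls, -0.29 ± 0.09 after fear conditioning at 3 months and -0.13 ± 0.31 at 16 months, and -1.37 ± 0.17 and -1.32 ± 0.10 in context and shock-context mice. Microglia and complement genes had means of -0.43 ± 0.05 and 0.09 ± 0.17 in young and old controls, -0.75 ± 0.07 and -0.04 ± 0.09 in young and old fear mice, and -0.98 ± 0.12 and -0.90 ± 0.11 in context and shock-context mice.

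The tests in this paragraph were chosen after the values were seen. Of the genes that separate the 8 young from the 8 old control and fear arrays by over 0.5, 15 in number, 10 have the 8 context and shock-context arrays, also young, on the young side, as an effect of age would give. On the old side lie 2: Wdfy1, with a mean of 1.44 in the 8 young arrays, -0.40 in the 8 old and -0.38 in the context and shock-context arrays, and the clone BB339336, named after its values were seen, with means of 2.00, 0.65 and 0.59. A genetic or colony difference of the young control and fear mice is a candidate explanation for these 2, which cannot be told apart from the scan run: the division of the same 16 arrays by training separates 9 genes, with 2 and 7 on its sides.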
